A study of Mus musculus with 4 samples.

How the data were processed

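Single-cell RNA sequencing had been done on bone marrow-derived macrophages (BMDMs), primary cells that grow out of mouse bone marrow in the macrophage growth factor M-CSF (50 ng/mL). Per the labels, the marrow came from mice aged 8 to 12 weeks, either wild type (C57BL/6J in the sample titles, C57BL/6 in the growth protocol) or Trpv4-null, and the cells were left untreated or were given bacterial lipopolysaccharide (LPS) at 100 ng/mL for 24 h. The series lists 4 samples, which fall into 4 groups of 1 library each. Its design text speaks of 3 mice per genotype, with and without LPS, and 12 samples, but the per-cell annotation used here names the library of each cell and no mouse. Each group was therefore treated as 1 library with an unknown mixture of mice, and no difference between groups has a replicate check.

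The deposited count table holds whole-number counts of unique molecular identifiers (UMIs, 1 per captured mRNA molecule) for 14432 genes in 27366 cells, not normalized. Per the submitters' processing notes, Cell Ranger 3.1.0, Seurat 4, R 4.2 and the mouse genome build mm10 were used, and no role or order is given for them. The deposited cell annotation gives, per the file headers, the UMI count of each cell, the fraction of its UMIs from the mitochondrial genome, the ratio of log10 genes detected to log10 UMIs, its library and the name the authors gave to its cluster. The authors' filters on cells are not given in the sources used here. In the deposited values every cell had between 1003 and 39987 UMIs, at most 9.998% mitochondrial UMIs and a ratio of at least 0.8003, and every gene was found in at least 6 cells. The counts of all 27366 cells summed to the UMI totals in the annotation. No statement on doublets is given in the sources used here, and strand use in counting is not stated either, so overlapping genes such as Oasl1 and Gm13822, and close relatives such as Ccl2, Ccl7 and Ccl12, may share counts.

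From these counts, UMIs were summed per library over all deposited cells and scaled by the library total to CPM, counts per 1000000 UMIs. Ratios between libraries were taken as log2 of CPM plus a pseudocount of 1 CPM, which understates the ratio of genes near that level. A gene was compared where it had at least 20 CPM, and at least 30 UMIs, in the higher library, and a ratio of 2-fold or more was counted as a size, not as a test. With 1 library per group, no p-value, standard error over replicates or count of changed genes was computed. CPM values carry exact Poisson 95% intervals, ratios of CPM exact conditional 95% intervals and shares of cells exact (Clopper-Pearson) 95% binomial intervals. All of them cover counting error only, not the spread between mice or cultures. Over the 316 named genes, the CPM interval in the library with the highest value had a median half-width of 1.96% of the value and at most 6.65% where the value reached 20 CPM. A ratio against 0 UMIs was taken against a floor of 3 UMIs and is given as a lower bound.

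Before the data were examined, the groups, the comparisons, the settings above, 27 gene lists, 13 lists of cell type markers, the rule for named genes and the alternatives were fixed, apart from those said to have been added. Named genes were the 12 with the highest and the 12 with the lowest log2 ratio of each comparison (10 each for the difference between the LPS responses of the genotypes, with at least 20 CPM in any library), Trpv4, up to 4 members of each gene list with the largest ratio, the NF-kB subunits and the cytokines Tnf, Il6, Il1b, Il12b, Il10, Il1rn, Nos2, Ccl2, Cxcl1, Cxcl2 and Cxcl10. Gene models without a name were skipped, and some genes that the rule names are not reported here. For each list, the median log2 ratio of its compared members was set against 10000 random lists of the same size matched on mean expression over 20 bins, and its percentile describes where the list lies in these libraries. The authors' clusters were used as they stand. Ratios within clusters were computed for the 8 clusters with at least 100 cells in each library, leaving out the cluster named High_Btg1. For shares of cells with a UMI, each cell was also thinned at random to 3000 UMIs and shallower cells were left out. Gene positions came from GENCODE release M21 on GRCm38, the assembly that mm10 names, where 14286 of the 14432 symbols (98.99%) matched.

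The computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for TMM factors alone. The ratio and list steps were tested on simulated counts with 100 genes set to 4-fold and 100 to 1.5-fold. For LPS in wild type (5494 genes) 99% of the 4-fold genes and none of the 1.5-fold or 5295 unchanged genes came out at 2-fold or more, and 95.0% of the intervals held the true ratio. For the genotypes under LPS (5108 genes) these values were 100%, none of the 1.5-fold genes, none of 4908 and 94.8%. Apart from the set genes, the simulated libraries differed by counting error alone, without spread between cultures or a shift of most genes by LPS. The test therefore checks the computation only and cannot show how either would change the results.

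As alternatives, the libraries were scaled by median-of-ratios size factors or TMM factors, mitochondrial and ribosomal protein genes were left out of the total, the pseudocount was set to 0.1 or 5 CPM, the CPM minimum to 50 or none, cells were weighted equally, and cells were limited to the cluster named Macrophage, to cells with less than 5% mitochondrial UMIs or to cells not called in S or G2/M phase. Cells were also clustered anew with Leiden at resolution 0.5 and 1.0. The doublet caller Scrublet marked 1 of 27366 cells (0.00365%), below the 0.5% under which a caller was taken not to have worked, so no doublets were removed. Alternatives added after the data had been seen were the removal of the 5% of cells with the most UMIs in each library and equal weights for the clusters in every library.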

Results

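The series title concerns the mechanosensitive, calcium-permeable channel TRPV4 and its relation to NF-kB signalling, the transcription factor pathway that drives much of the inflammatory response, in lung inflammation. The data were single-cell transcriptomes of macrophages grown from the bone marrow of wild-type mice and of mice labelled Trpv4-null, untreated or after 24 h of LPS, a bacterial cell wall component sensed through TLR4. There was 1 library per group, so values are given with counting intervals and without tests. The untreated wild-type library held 7028 cells and 43731003 UMIs, and the untreated library labelled Trpv4-null 5485 cells and 47000669 UMIs. After LPS, the wild-type library held 8288 cells and 144090985 UMIs and the library labelled Trpv4-null 6565 cells and 109030958 UMIs. The median cell had 5660.5 and 7893 UMIs in the untreated libraries and 16673.5 and 16041 UMIs after LPS, in the order wild type and labelled Trpv4-null.

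The cells carried macrophage transcripts throughout. All 14 macrophage markers, among them the lysozyme gene Lyz2, reached at least 20 CPM in each of the 9 clusters named by the authors, and Lyz2 stood at 14340 to 22520 CPM in the 4 libraries. Of 10 monocyte markers, 4 reached 20 CPM in a library, led by Ms4a4c with 11.4 and 17.1 CPM in the untreated libraries (wild type and labelled Trpv4-null) and 825 and 935 CPM after LPS. Of 13 dendritic cell markers, Irf8 alone did, with 346 and 365 CPM untreated and 185 and 201 CPM after LPS, as did 2 of 7 osteoclast markers, led by Nfatc1 (at most 45.6 CPM), and the eosinophil marker Ccr3 (at most 24.8 CPM). Of 9 neutrophil markers in the table, 5 reached 20 CPM in a library, and the neutrophil granule gene S100a9 had 94.1 and 153 CPM in the untreated libraries (wild type and labelled Trpv4-null) and 19.9 and 6.75 CPM after LPS. Between 98.1% and 99.6% of the S100a9 UMIs of a library came from 6 (wild type, untreated), 5 (wild type, LPS), 10 (labelled Trpv4-null, untreated) and 1 (labelled Trpv4-null, LPS) cells. Of the B cell markers, the immunoglobulin gene Ighm alone passed 20 CPM, with 134 and 137 CPM in the untreated libraries. No marker of erythroid, T, mast, stromal, endothelial or progenitor cells that was in the table reached 20 CPM. Many of these markers were not in it. The table held 1 of 8 erythroid, 2 of 11 T or NK, 3 of 10 mast, 4 of 12 stromal, 4 of 7 endothelial and 8 of 9 progenitor markers.

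Trpv4 itself, the targeted gene, was not lower in the libraries labelled Trpv4-null. The gene lies on the minus strand of chromosome 5 at 114622152 to 114658421 (GRCm38). It had 255 UMIs (5.83 CPM, 95% interval 5.14 to 6.59) in the untreated wild-type library and 404 (8.60 CPM, 7.78 to 9.48) in the untreated library labelled Trpv4-null, a ratio of 1.47 (1.26 to 1.73). After LPS it had 298 UMIs (2.07 CPM, 1.84 to 2.32) in wild type and 1049 (9.62 CPM, 9.05 to 10.2) in the library labelled Trpv4-null, a ratio of 4.65 (4.09 to 5.31). LPS went with a lower Trpv4 level in wild type under each scaling (ratio 0.355, 0.299 to 0.421, by total and 0.513, 0.433 to 0.609, with median-of-ratios size factors). In the libraries labelled Trpv4-null the interval held 1 by total scaling (1.12, 0.997 to 1.26) but not with median-of-ratios size factors (1.71, 1.52 to 1.92) or TMM factors (1.68, 1.49 to 1.88). The share of cells with a Trpv4 UMI was 3.41%, 3.49%, 6.91% and 14.4% in the order wild type untreated, wild type LPS, labelled Trpv4-null untreated and labelled Trpv4-null LPS. In cells thinned to 3000 UMIs it was 1.96%, 0.771%, 2.60% and 3.07%, with 666, 122, 209 and 93 shallower cells left out. Within the 8 clusters compared, the log2 ratio of the genotypes lay between 1.40 and 2.25 after LPS and between -0.036 and 1.72 untreated, where it was above 0 in 7 and below 0 in 1. The part of the gene that was deleted and the position of the reads are not given in the sources used here, and counts from outside the deleted part would check nothing. No cluster of a cell type that should lack Trpv4 was present to measure free RNA. The genotype is therefore given below as a label, and every direction between genotypes rests on that label.

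**Figure D1:**
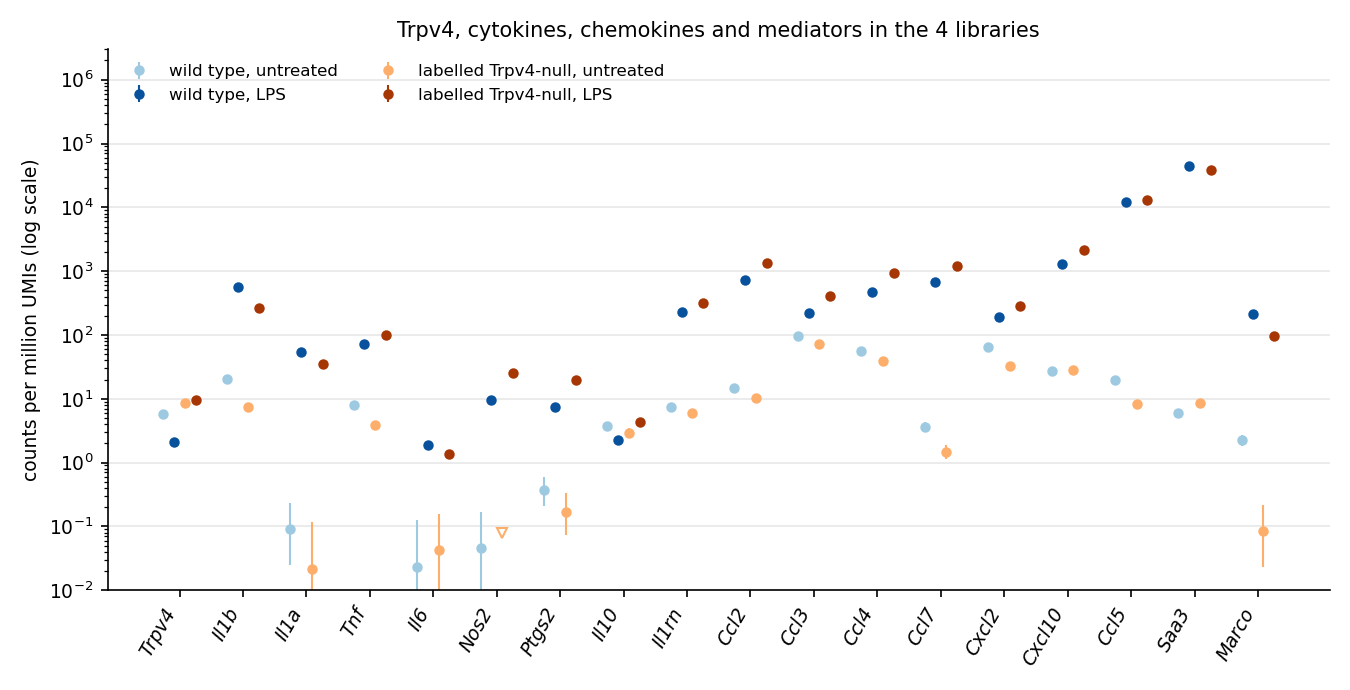
CPM (log scale) of Trpv4 and of cytokines, chemokines and mediators in the 4 libraries; points are library values and bars exact Poisson 95% intervals, which cover counting error only. Trpv4 stood at 9.62 CPM after LPS in the library labelled Trpv4-null and at 2.07 CPM in wild type, while Il1b stood at 263 and 573 CPM.

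In wild-type cells, LPS went with acute-phase, chemokine and interferon transcripts far above the untreated level. Saa3, an acute-phase serum amyloid, stood at 5.88 CPM untreated and at 44660 CPM after LPS, a ratio of 7600 (6725 to 8622). The chemokine Ccl5 stood at 19.6 and 12150 CPM (ratio 622, 581 to 666), and Acod1, which makes itaconate, at 2.20 and 1236 CPM. The chemokines Ccl12 and Ccl7, the formyl peptide receptors Fpr1 and Fpr2, the NAD-consuming enzyme Cd38, Ifi205, the prostaglandin E synthase Ptges, the complement factor Cfb and the matrix metalloprotease Mmp14 completed the 12 highest, with log2 ratios of 6.24 to 7.63. At the other end, the iron exporter Slc40a1 stood at 447 CPM untreated and 4.64 CPM after LPS (log2 -6.31), Cd28 at 222 and 2.69 CPM, and the transcriptional regulator Id3 at 145 and 1.89 CPM. Ighm (log2 -6.93), the prostaglandin-degrading enzyme Hpgd, Gpr34, Samd4, Gprc5c, the anion transporter Slco2b1, Sulf2, Ramp1 and Cytip were the other lowest, down to -4.76.

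The inflammatory gene lists moved together in wild type. Of 40 interferon-stimulated genes compared, 39 were at least 2-fold higher (median log2 3.50), with Isg15 at 32.2 and 1854 CPM and the interferon regulatory factor Irf7 at 28.3 and 1131 CPM. Of 12 chemokines, 10 were at least 2-fold higher (4.22), and of 10 pro-inflammatory cytokines and mediators 7 were (4.34). Il1b stood at 20.2 and 573 CPM, Tnf at 8.12 and 70.9 CPM and Il6 at 0.0229 and 1.92 CPM, while Il12b stayed near 0.1 CPM (0.137 and 0.153). Antigen presentation (1.10), glycolysis and hypoxia (0.99) and NF-kB subunits and inhibitors (0.73) lay above all 10000 matched random lists. Within the last list the inhibitors and adaptors Traf1 (2.52), Nfkbia (1.66), Nfkbie (1.53) and Tnfaip3 (1.45) were highest, and the subunits Nfkb2 (0.72) and Relb (0.41) were higher and Rel (-1.15) lower than untreated, while Nfkb1 (-0.26) and Rela (-0.33) turned above 0 with median-of-ratios size factors (0.27 and 0.19). Genes of the G2 and M phases (-1.57, 15 of 16 lower), immediate-early genes (-1.11, with Egr1 at 47.6 and 1.25 CPM), mitochondrial genome transcripts (-1.04), MAPK pathway genes (-0.79) and ribosomal proteins (-0.74) lay below at least 99% of random lists.

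The highest genes in the libraries labelled Trpv4-null were largely those of wild type. Saa3 (log2 11.98), Ccl5 (10.44), Ccl7 (8.95), Acod1 (8.90) and Ccl12 (8.14) led again, and Ccl8, Ccl2 and the scavenger receptor Marco (6.48) entered the 12 highest. Ighm (-7.06), Slc40a1 (-6.42) and Cd28 (-6.32) were again lowest. The list medians were 3.21 for interferon-stimulated genes (39 of 40 at least 2-fold higher), 5.10 for chemokines (11 of 12), 4.72 for pro-inflammatory cytokines (8 of 11, and 4.97 with Nos2, at 0 UMIs untreated, set to its lower bound), 1.13 for antigen presentation, 0.98 for NF-kB subunits and inhibitors and 0.68 for glycolysis and hypoxia. They were -1.82 for G2 and M phase, -0.80 for immediate-early genes, -1.07 for mitochondrial transcripts and -0.93 for ribosomal proteins. The MAPK list (-0.67), the anti-inflammatory list (-0.55) and actin and adhesion (-0.49) lay within the central 95% of random lists here (percentiles 8.03, 16.44 and 6.67), but below it in wild type (0.98, 0.04 and 1.47). Taken gene by gene, the median difference between the LPS log2 ratios of the genotypes was 0.083, 0.095 and 0.061 for these lists. The MAPK and anti-inflammatory differences lay above the central 95% of random lists (percentiles 99.46 and 99.12), and that of actin and adhesion within it (95.21). Nos2, the inducible nitric oxide synthase, had 0 UMIs untreated and 25.3 CPM after LPS, at least 396-fold higher. In wild type it had 2 UMIs untreated and 9.42 CPM after LPS, a ratio of 206 (56.9 to 1702). Across 6471 genes, which are not independent replicates, the LPS log2 ratios of the genotypes had a Pearson correlation of 0.982.

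**Figure D2:**
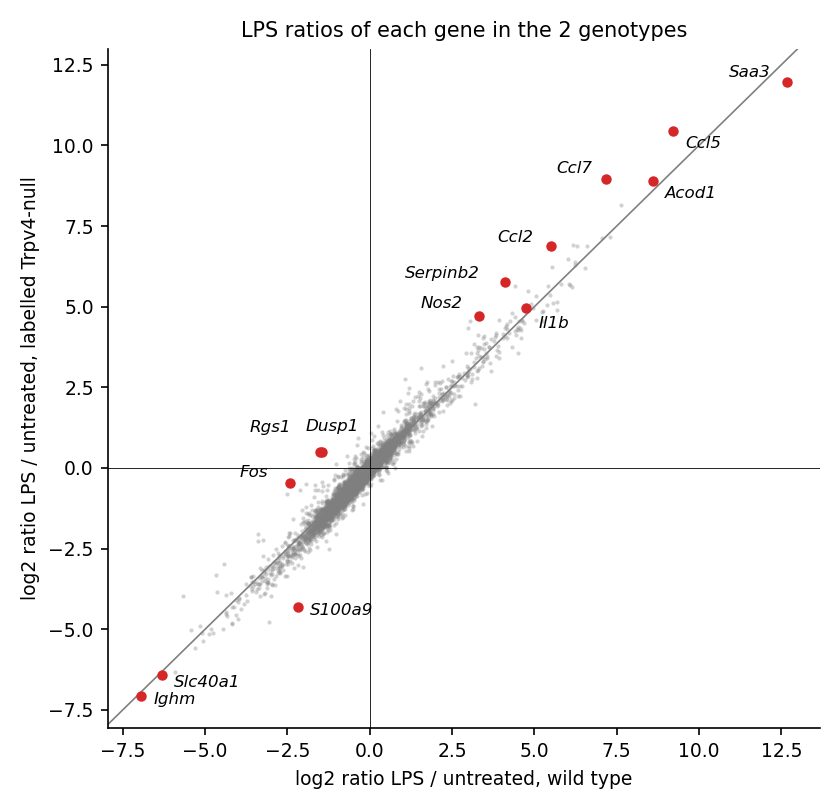
Each point is a gene, with its log2 ratio LPS over untreated in wild type (horizontal axis) and in the libraries labelled Trpv4-null (vertical axis), scaled by total UMIs, and the line marks equal ratios. The genes follow the line (r = 0.982 across 6471 genes), with Saa3 at 12.67 and 11.98 at the far end.

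By total scaling the median gene lay at a log2 ratio of -0.39 in wild type and -0.42 in the libraries labelled Trpv4-null. Fth1, the ferritin heavy chain, held 3.94% of the wild-type UMIs untreated and 11.1% after LPS, and 3.60% and 10.7% of those labelled Trpv4-null. Of 6332 genes compared in wild type, 437 were at least 2-fold higher and 1121 lower (28.0% higher), and of 6340 labelled Trpv4-null 463 and 1348 (25.6%). With median-of-ratios size factors the median gene lay at 0.20 and 0.27, and the counts were 829 higher and 377 lower (68.7%) and 988 and 419 (70.2%). With TMM factors they were 815 and 379 (68.3%) and 947 and 435 (68.5%). The inflammatory lists lay above 0, and the G2 and M phase, immediate-early, mitochondrial, MAPK and ribosomal lists below 0, under each of these scalings. The nuclear-encoded oxidative phosphorylation (0.30 and 0.19 in wild type and labelled Trpv4-null), unfolded protein response (0.51 and 0.32), S phase (0.33 and 0.28) and cholesterol lists (0.08 and 0.12) lay above at least 96% of random lists, though the S phase medians lay below 0 when cells called in S or G2/M phase were removed. Other lists took their side from the scaling. The lists of phagocytic receptors (-0.50 and -0.26), oxidative stress (-0.35 and -0.16) and mechanosensitive and calcium channels (-0.46 and -0.45) turned above 0 in both genotypes with median-of-ratios size factors. So did lysosome (-0.39), actin and adhesion (-0.49), anti-inflammatory (-0.55) and chromosome 5 neighbours of Trpv4 (-0.53) in the libraries labelled Trpv4-null, but not in wild type (by total -0.54, -0.60, -1.32 and -0.54). These factors raise log2 ratios by about 0.53 in wild type and 0.61 in the libraries labelled Trpv4-null. The wild-type medians of -0.54 were thus only just below 0 with them. TLR4 signalling (-0.13 and 0.02), heat shock (0.25 and 0.23), matrix remodelling (-0.60 and 0.12) and housekeeping genes (0.10 and -0.04) lay within the central 95% of random lists in both genotypes.

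Between the untreated libraries, the library labelled Trpv4-null had more transcripts of Mmp8, cell division and interferon genes and fewer immediate-early transcripts, although the Trpv4 counts did not follow the label. The collagenase Mmp8 stood at 9.19 CPM in wild type and 43.4 CPM in the library labelled Trpv4-null (ratio 4.72, 4.24 to 5.27), the cell surface protein Ly6a at 4.92 and 22.1 CPM (4.50, 3.88 to 5.24) and the aryl hydrocarbon receptor repressor Ahrr at 7.89 and 26.2 CPM (3.32, 2.94 to 3.75). Mmp8 is a neutrophil marker too, and its ratio was above 0 in all 8 clusters compared (log2 0.998 to 2.54). Gpr141 (1.42), the mitosis genes Nusap1 (1.07), Top2a (1.05), Prc1 (1.04) and Plk1 (1.01), Tiparp (0.99), Gcn1l1, Lockd and Irf7 (0.91) were the other highest. The phosphatase gene Dusp1 stood at 326 and 111 CPM (ratio 0.340, 0.330 to 0.351), Fos at 467 and 185 CPM (0.396, 0.386 to 0.406), Fosb at 186 and 70.7 CPM and Il1b at 20.2 and 7.43 CPM (0.367, 0.324 to 0.416). Id3 (-1.23), Cd83 (-1.15), Rgs1 (-1.12), Cxcl2 (-0.97), Egr1 (-0.90), Ell2 and Myo1e followed.

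Few genes were this far apart. Of 6156 genes, 9 were at least 2-fold higher and 9 lower in the library labelled Trpv4-null, and 97.4% lay within 0.5 on the log2 scale. With median-of-ratios size factors or TMM factors, 5 were higher and 8 lower (38.5% higher against 50.0%). Of 15 immediate-early genes, 14 were lower (median -0.42, below all random lists). Of 12 anti-inflammatory and alternative activation genes 8 were lower (-0.28), among them Pparg, Klf4, Socs3 and the mRNA-decay factor Zfp36 (-0.71). The other 4 were higher, and Folr2, on the same list, had a log2 ratio of 0.66. The MAPK list (-0.17) and the oxidative stress list (-0.16, 15 of 19 lower, with Txnrd1 at -0.65 and Hmox1 at -0.55) were also below at least 99.9% of random lists. All 26 G2 and M phase genes compared (0.66) and all 27 interferon-stimulated genes (0.36, with Gbp2 at 0.91 and Zbp1 at 0.69) were higher. Weighting the clusters equally in every library took these medians to 0.10 and 0.18, and without cells called in S or G2/M phase the G2 and M median was -0.001. Matrix remodelling (0.17), cholesterol (0.11) and oxidative phosphorylation (0.05) lay above at least 99% of random lists. NF-kB subunits and inhibitors had a median of -0.09 (percentile 2.97), with Nfkb1 at -0.25, Rela at -0.16 and Nfkbiz at -0.81. Pro-inflammatory cytokines (0.003, 3 genes), chemokines (-0.08), TLR4 signalling (-0.08), heat shock (-0.10) and the neighbours of Trpv4 (-0.04) lay within the central 95% of random lists. Xist, the sex-linked gene compared, stood at 1006 and 898 CPM untreated and at 564 and 495 CPM after LPS.

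After LPS, chemokine, matrix and antigen presentation transcripts were higher, and Il1b and glycolytic transcripts lower, in the library labelled Trpv4-null, again by a label that the Trpv4 counts did not follow. Serpinb2, a plasminogen activator inhibitor, stood at 16.9 CPM in wild type and 58.0 CPM in the library labelled Trpv4-null (ratio 3.43, 3.27 to 3.59), the metalloproteases Mmp13 at 16.0 and 47.7 CPM (2.98, 2.84 to 3.13) and Mmp12 at 13.8 and 33.0 CPM (2.39, 2.26 to 2.52), and Nos2 at 9.42 and 25.3 CPM (2.68, 2.51 to 2.86). The chemokine Ccl4 stood at 463 and 938 CPM (2.03, 2.01 to 2.05) and Ccl2 at 727 and 1324 CPM (1.82, 1.81 to 1.84). Ly6a (1.03), Gpnmb (0.96), Col18a1, Il7r, Rgs1 (0.87) and Emp1 were the other highest. Marco, a scavenger receptor, was lower at 211 and 95.6 CPM (0.453, 0.443 to 0.464), as were Il1b at 573 and 263 CPM (0.460, 0.453 to 0.466) and the inhibitory receptor Cd33 at 46.7 and 21.7 CPM. Fam162a (-0.83), Clec4n (-0.81), the ATP-gated channel P2rx7 (-0.79), Ide, Bnip3 (-0.70), Gltp (-0.65), Il1a (-0.64) and Rnf34 were also among the 12 lowest.

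Here 7 of 5236 genes were at least 2-fold higher and 3 lower, and 98.2% lay within 0.5 on the log2 scale. All 12 chemokines compared were higher (median 0.67), 1 of them at least 2-fold, among them Ccl7 at 676 and 1223 CPM, Ccl3 at 223 and 402 CPM and Cxcl10 at 1310 and 2173 CPM. Of 11 pro-inflammatory cytokines and mediators, 6 were higher and 5 lower (0.11). Tnf stood at 70.9 and 98.6 CPM (ratio 1.39, 1.35 to 1.43), Il10 at 2.28 and 4.31 CPM (1.89, 1.64 to 2.18), the interleukin-1 receptor antagonist Il1rn at 231 and 312 CPM and Il6 at 1.92 and 1.36 CPM (0.709, 0.576 to 0.868). Of 22 glycolysis and hypoxia genes, 20 were lower (-0.30), with Pfkl (-0.57), the lactate exporter Slc16a3 (-0.54) and hexokinase 2, Hk2 (-0.53). Matrix remodelling (0.42), antigen presentation (0.19, with H2-Aa at 0.81 and Cd74 at 0.80), interferon-stimulated genes (0.20, 37 of 40 higher), immediate-early genes (0.20, 7 of 12 higher) and cholesterol genes (0.13) lay above at least 99.9% of random lists. Taken per cluster, H2-Aa stood at 651.1 CPM in the cluster named Cd74+ and at no more than 31.02 CPM in any other. After LPS that cluster held 2.33% of wild-type cells and 3.53% of those labelled Trpv4-null. The H2-Aa ratio may therefore come in part from a difference in the share of that cluster, and its ratio within clusters is not given here. Cd74 was higher in all 8 clusters compared (0.146 to 1.134). The G2 and M list was also higher (0.38, 9 of 9 genes), but its median was -0.03 without cells called in S or G2/M phase and 0.06 with equal cluster weights. NF-kB subunits and inhibitors had a median of 0.03 (percentile 98.11), with Nfkb1 at -0.18, Rela at 0.08, Relb at 0.13, Rel at -0.02 and Nfkb2 at -0.01. Phagocytic receptors and lysosome genes had medians of 0.08 each. TLR4 signalling (-0.05), the MAPK list (-0.03), the anti-inflammatory list (-0.01) and the neighbours of Trpv4 (-0.04) lay within the central 95% of random lists, and each of these 4 medians lay above 0 with median-of-ratios size factors.

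**Figure D3:**
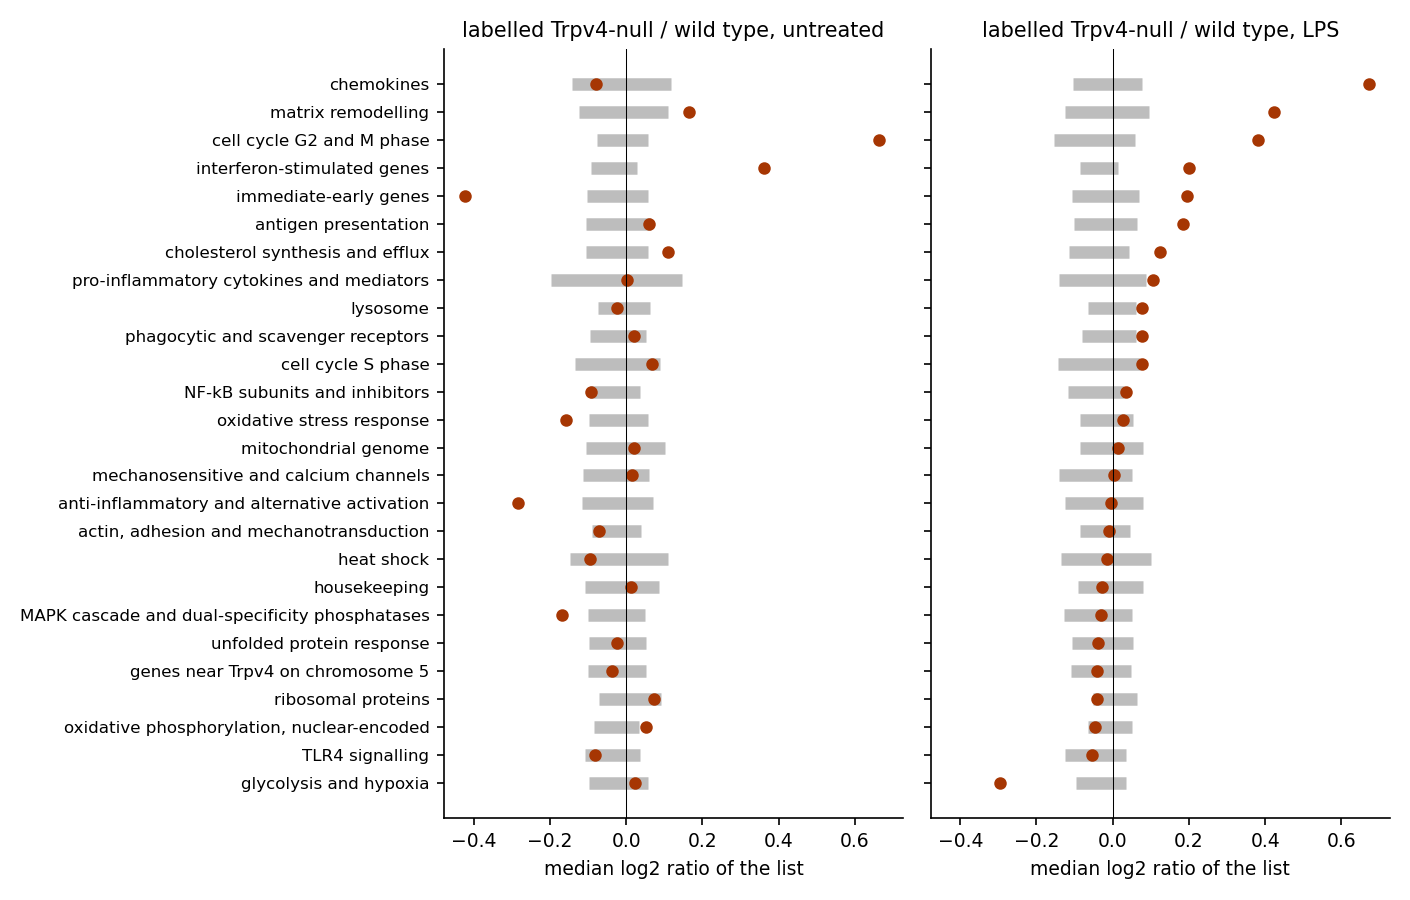
Median log2 ratio, library labelled Trpv4-null over wild type, of each gene list in the untreated pair and in the LPS pair, with bars for the central 95% of 10000 random lists of the same size matched on expression. Chemokines lay at -0.08 untreated and 0.67 after LPS, immediate-early genes at -0.42 and 0.20, and glycolysis and hypoxia at 0.02 and -0.30. The members compared differ between the pairs, with 7 and 12 chemokines, 15 and 12 immediate-early genes, and 17 and 22 glycolysis and hypoxia genes.

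The difference between the LPS log2 ratios of the genotypes was largest for immediate-early genes and chemokines. It was 1.99 for the signalling regulator Rgs1, 1.97 for Fos, 1.95 for Dusp1, 1.77 for Ccl7, 1.72 for Fosb, 1.70 for Id3, 1.68 for the cyclin Ccnd1, 1.67 for Serpinb2, 1.55 for Cxcl2 and 1.52 for Ccl4. Dusp1 stood at 326 and 119 CPM in wild type, untreated and after LPS, and at 111 and 158 CPM in the libraries labelled Trpv4-null. Rgs1, Fos, Dusp1, Ccl7, Fosb, Id3, Ccnd1 and Cxcl2 owed the larger part of the difference to the untreated pair. The parts were close for Ccl7 (-0.917 untreated and 0.855 after LPS), which stood at only 3.659 and 1.468 CPM in the untreated libraries. Serpinb2 and Ccl4 owed the larger part to the LPS pair, and Serpinb2 had under 0.1 CPM in both untreated libraries. The lowest differences were those of the neutrophil genes S100a9 (-2.13), Ngp (-1.71) and S100a8 (-1.29), of which S100a9 came from the few cells described above, followed by Wfdc21 (-1.19), the metallothionein Mt2 (-1.04), Kansl2, Bmf, Ly6a (-0.94), Fh1 and Cd33. Of 6471 genes, 35 had a difference of 2-fold or more upward and 6 downward. Of these 41, the larger part lay in the untreated pair for 25 and in the LPS pair for 16. The list medians were 0.96 for chemokines (12 of 12 higher), 0.51 for immediate-early genes and 0.18 for NF-kB subunits and inhibitors, each above all random lists. Glycolysis and hypoxia (-0.32, 19 of 23 lower) and interferon-stimulated genes (-0.14, 31 of 40 lower) lay below all of them, the latter at -0.04 with equal cluster weights.

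Several genotype differences were found in more than a single cluster. Il1b was lower in the library labelled Trpv4-null in all 8 clusters, untreated (-2.26 to -0.27) and after LPS (-1.47 to -0.78), the cluster that the authors named Il1b+_Cxcl2+ included. After LPS, Ccl2 (0.66 to 1.07), Ccl4 (0.57 to 1.64), Tnf (0.36 to 0.69), Nos2 (0.68 to 1.71) and Gpnmb (0.84 to 1.59) were higher in all 8. Fos (-1.56 to -0.99), Dusp1 (-1.80 to -1.27) and Rgs1 (-1.51 to -0.72) were lower in all 8 in the untreated pair and higher in all 8 after LPS. Among the list medians, chemokines were higher in all 8 after LPS (0.34 to 0.84), glycolysis and hypoxia genes lower in all 8 (-0.40 to -0.12), and untreated immediate-early genes lower in all 8 (-0.62 to -0.14). The pro-inflammatory cytokine list was mixed, higher in 4 and lower in 4 clusters after LPS (-0.039 to 0.13) and higher in 5 and lower in 3 untreated (-0.20 to 0.21), and heat shock genes were lower in all 8 untreated (-0.17 to -0.028) and higher in 3 and lower in 5 after LPS (-0.21 to 0.13). The largest cluster, named Macrophage, held 37.7%, 28.9%, 35.4% and 26.7% of cells in the order wild type untreated, wild type LPS, labelled Trpv4-null untreated and labelled Trpv4-null LPS. The cluster named Ifit1bl1+_Cmpk2+ held 2.52%, 10.4%, 3.26% and 11%, and the cluster named Proliferating 5.99%, 7.26%, 9.88% and 9.81%. Since the genes that name clusters differed between libraries, no order is read from these shares.

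**Figure D4:**
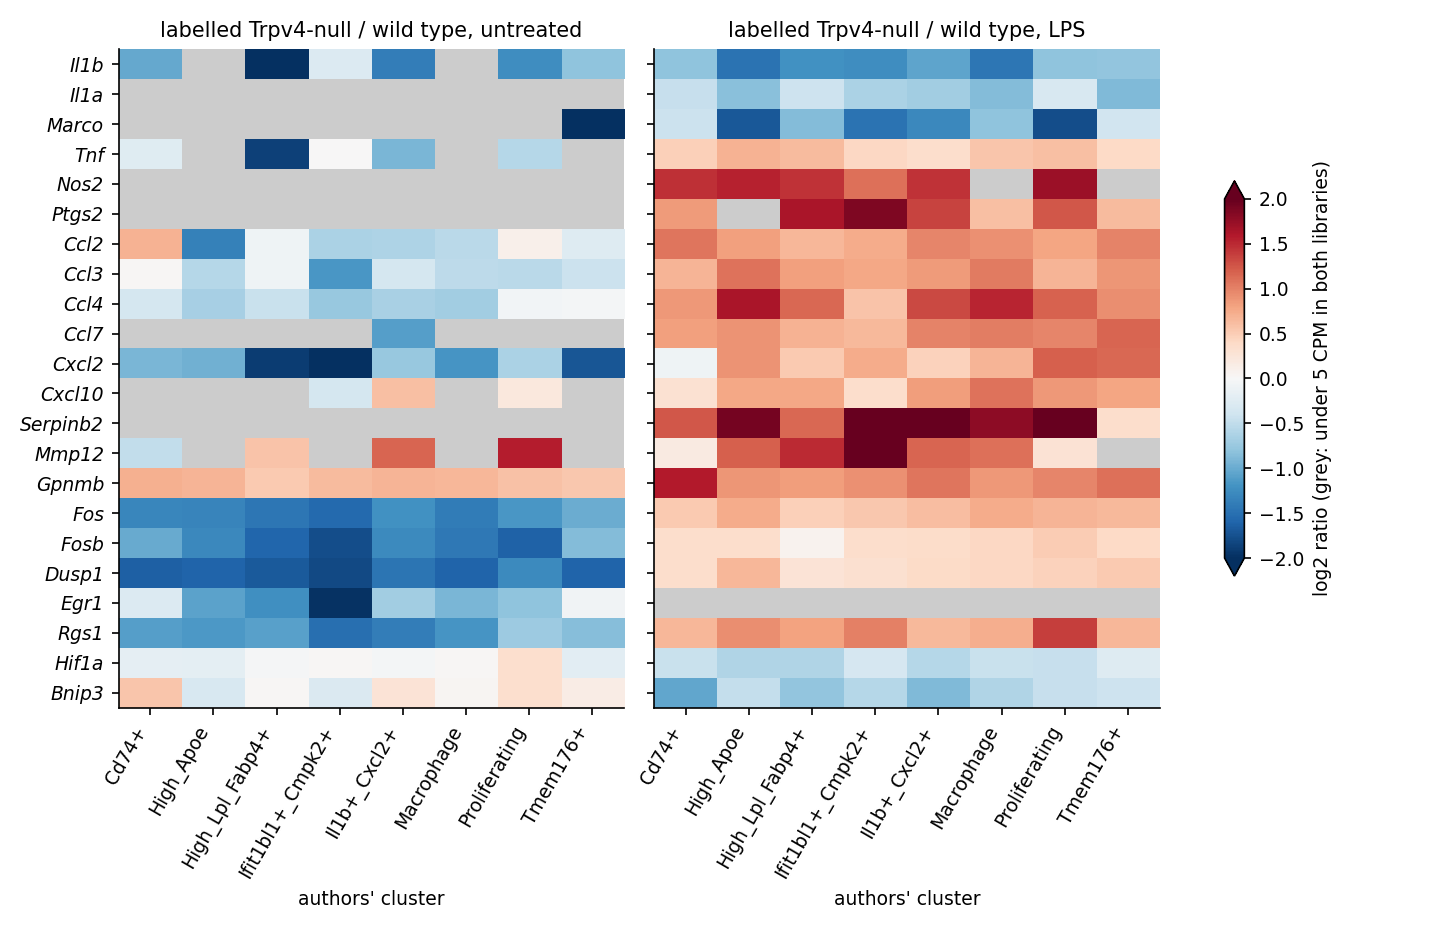
Log2 ratio, library labelled Trpv4-null over wild type, of selected genes (vertical axis) within each of the authors' clusters with at least 100 cells per library (horizontal axis), untreated and after LPS. Grey marks values under 5 CPM in both libraries. Il1b was lower in all 8 clusters in both pairs, 2 of them grey untreated, and Fos, Dusp1 and Rgs1 were lower in all 8 untreated and higher in all 8 after LPS.

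Around Trpv4 on chromosome 5, several neighbouring genes differed the same way in both pairs. Of 116 genes compared within 10 Mb on either side, 9 (7.76%) differed by 0.3 or more on the log2 scale in the same direction untreated and after LPS, against 125 of 6308 elsewhere (1.98%). Of 3876 overlapping windows of as many genes elsewhere, 84 had a share as high, so this window lay at percentile 97.83. Neighbouring windows shared most of their genes, so the 84 are not independent and may come from few regions. The 9 genes, named after their values were seen, were Dr1, Idua, Mvk, Gltp (-0.51 untreated and -0.65 after LPS), 1500011B03Rik, Gm13822, Oasl1 (1.39 and 0.62), Coq5 and P2rx7 (-0.49 and -0.79). Across these 116 genes the log2 ratios of both pairs had a Pearson correlation of 0.698 and a Spearman correlation of 0.601, against a Pearson correlation of 0.273 over genes elsewhere. Over the whole genome, 39 genes differed by 0.5 or more in the same direction in both pairs (28 higher, 11 lower), 7 of them on chromosome 5. Among those elsewhere, picked out after their values were seen, were Mmp8 (2.12 and 1.69) and Mmp13 (1.36 and 1.52) on chromosome 9, and Ctsl (0.90 and 0.74), which encodes the lysosomal protease cathepsin L, on chromosome 13.

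**Figure D5:**
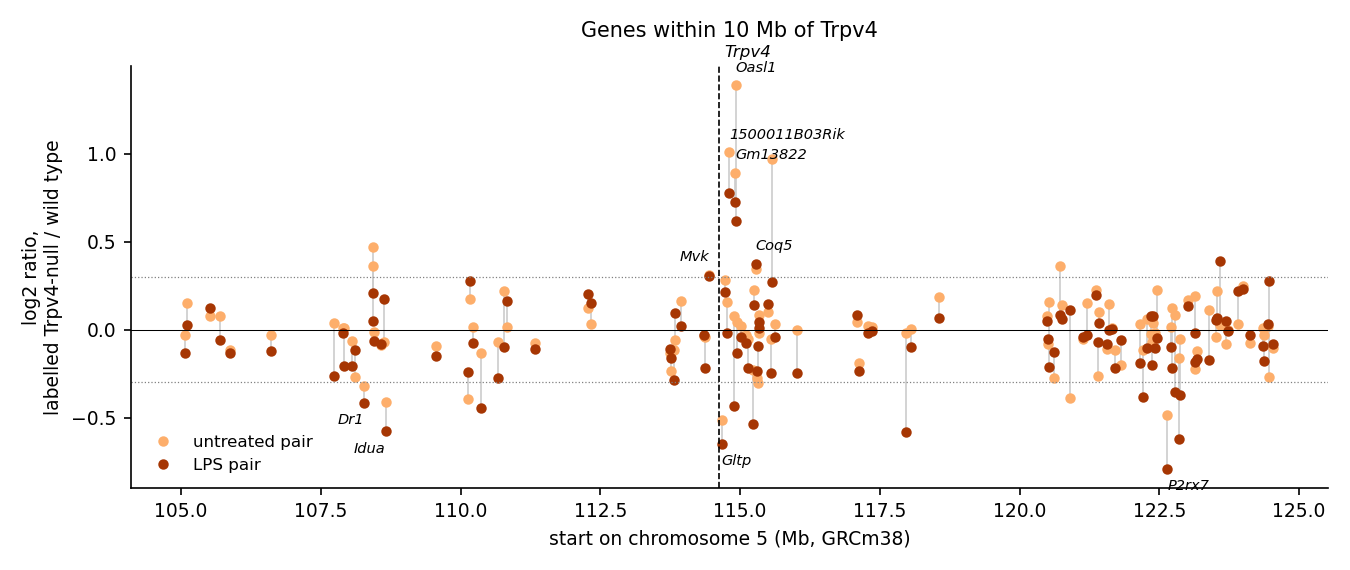
Log2 ratio, library labelled Trpv4-null over wild type, of each gene compared within 10 Mb of Trpv4 against its start on chromosome 5 (Mb, GRCm38), for the untreated pair and the LPS pair. Of the 116 genes, 9 passed 0.3 in the same direction in both pairs, with Gltp at -0.51 and -0.65.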

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

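The tests of exchanged genotype labels, of depth in both pairs, of a segment linked to the Trpv4 locus, of handling and both tests of scaling were chosen only after the results they bear on had been seen.

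A few named genes had LPS ratios, scaled by total, on opposite sides of 0 in wild type and in the libraries labelled Trpv4-null, by counting intervals that exclude a ratio of 1 in both, which is why they stand here. The difference of log2 ratios, labelled Trpv4-null minus wild type, was 1.985 for Rgs1, 1.947 for Dusp1, 0.966 for Il10, 0.821 for Cd36, 0.766 for Atf3 and 0.581 for Tgm2. Each was lower after LPS in wild type and higher after LPS in the libraries labelled Trpv4-null. These differences were not tested, since each group was 1 library. The wild-type ratios of Cd36 (-0.46), Atf3 (-0.47) and Tgm2 (-0.46) lay close to that of the median gene (-0.39), and turned above 0 with median-of-ratios size factors (0.072, 0.053 and 0.058) and with TMM factors (0.062, 0.044 and 0.049), so their opposite sides rest on scaling by total. Rgs1 (-0.97 and -0.98) and Dusp1 (-0.91 and -0.92) still lay below 0 in wild type with these factors, beyond counting error. The wild-type ratio of Il10 was 0.886 (0.732 to 1.08) and 0.880 (0.727 to 1.07) with them, an interval that holds 1, so its opposite sides rest on scaling by total too. For Rgs1 and Dusp1 the larger part of the difference lay in the untreated pair. The log2 ratio of the genotypes was -1.116 untreated and 0.869 after LPS for Rgs1, and -1.546 and 0.401 for Dusp1. A difference in handling of the untreated libraries, taken up below for immediate-early genes, was not tested for Rgs1 and Dusp1.

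Trpv4 transcripts were higher, not lower, in both libraries labelled Trpv4-null. If the genotype labels of 1 treatment alone had been exchanged, the genotype ratios of genes around Trpv4 would run opposite ways in the untreated and the LPS pair, but across the 116 genes within 10 Mb they correlated at 0.698, which argues against it. Deeper cells are argued against in the LPS pair, where the median cell of the library labelled Trpv4-null had 0.962 times the UMIs of wild type. In the untreated pair its cells were deeper, but the ratio of the shares of cells with a Trpv4 UMI after thinning to 3000 UMIs was 1.32 (1.03 to 1.70), only just clear of 1, and the CPM ratio, which takes depth out, was 1.47 (1.26 to 1.73), which argues against depth as the whole cause. An exchange of the labels in both treatments, and tags from a part of the gene that the deletion leaves in place, were not tested and stay open, as does a transcript made from the targeted allele.

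Around Trpv4, 9 of 116 genes (7.76%) differed alike in both pairs, against 1.98% elsewhere, as a segment of another strain linked to the targeted locus could give with and without LPS. The share of genes that differed alike lay at percentile 97.83 of 3876 overlapping windows elsewhere. This is between the bounds of 95 and 99 set for and against a linked segment. By this share, such a segment cannot be told apart from a chance run. The share takes no account of distance. Gltp, 1500011B03Rik, Gm13822 and Oasl1, the 4 genes of this window at or beyond 0.5 in both pairs, started 47 to 301 kb from the start of Trpv4. Mvk and Coq5 lay at -178 and 658 kb, and Dr1, Idua and P2rx7 at -6353, -5962 and 8022 kb. These distances were looked at afterwards and were not tested, nor was the larger correlation near Trpv4 (0.698, against 0.273 elsewhere). Scaling of the libraries is argued against, since a factor per library moves every gene the same way. Of the 9 genes that differed alike, 5 were higher and 4 lower. Such a segment does not cover the other chromosomes, and of the 39 genes at or beyond 0.5 in both pairs 7 lie on chromosome 5. No biological explanation through loss of Trpv4 could be tested, since the genotype label had no other check.

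Immediate-early genes were lower in the untreated library labelled Trpv4-null (median -0.42, 15 genes compared) and higher after LPS (0.20, 12 genes compared). Different shares of the authors' clusters are argued against, since with equal cluster weights the untreated median was -0.451, and scaling is too, since a factor per library moves every gene alike, whereas the list lay -0.40 from the median of all genes, outside the central 95% of random lists. A difference in handling, such as the time or warmth of cell dissociation, would lower these genes in every cluster and might move heat shock genes with them. The immediate-early and heat shock medians were both below 0 in all 8 clusters and 7 of 7 heat shock genes were lower, which goes with handling, but the heat shock median was -0.095, short of the bound of -0.2 and within the central 95% of random lists, so handling cannot be told apart from an effect of genotype. With 1 library per group, library preparation and genotype are confounded, and an effect of genotype stays open as untested.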

How the results depend on the processing

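The removal of the 5% of cells with the most UMIs and the equal cluster weights were chosen only after the results had been seen. Among named genes, 276 values of 2-fold or more gave 3588 values over 13 alternatives. Of these, 3586 had the same sign and 3386 were still 2-fold or more. Part of this sameness holds by construction. A change of the CPM minimum alters which genes are compared and leaves the ratio of each gene as it was. The lists kept the members of the reported setting under every alternative, so this change left their medians as they were too. A pseudocount cannot turn the sign of a ratio between libraries. Of list medians, 1419 values under alternatives stayed within 0.1 of the reported median (log2), 251 moved further and 20, each of 0.3 or more in size as reported, changed sign, and 96 of the 130 counts of genes stayed within 1.5 times the reported count. Among the shares of cells, 25 of 28 moved with thinning. The cause was not tested for any value given here, unless its construction shows it.

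Scaling mattered most for LPS. In wild type 829 genes were at least 2-fold higher and 377 lower with median-of-ratios size factors and 815 and 379 with TMM factors, and in the libraries labelled Trpv4-null 988 and 419, and 947 and 435. Both scalings left 5 genes higher in the untreated library labelled Trpv4-null, and 2 and 3 genes lower by the difference between LPS responses. In wild type the LPS medians turned above 0 for phagocytic receptors (0.027 with median-of-ratios and 0.017 with TMM factors), oxidative stress (0.18 and 0.17) and mechanosensitive and calcium channels (0.066 and 0.056). In the libraries labelled Trpv4-null they did so for the anti-inflammatory list (0.062 and 0.035), lysosome (0.22 and 0.19), mechanosensitive and calcium channels (0.16 and 0.13), actin and adhesion (0.118 and 0.091) and the neighbours of Trpv4 (0.062 and 0.036). The construction shows the cause, since these factors shift every gene of a library by the same amount.

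With a pseudocount of 0.1 CPM, 10 genes were lower by the difference between LPS responses and the log2 ratio of Trpv4 between genotypes under LPS was 2.17, and with 5 CPM these were 2 and 1.05 and 4 genes were higher in the untreated library labelled Trpv4-null. The pseudocount pulls low genes toward 0 by construction. Without the CPM minimum, more genes were compared and the counts higher and lower were 665 and 2016 for LPS in wild type, 704 and 2568 for LPS labelled Trpv4-null, 27 and 22 between genotypes untreated, 17 and 13 under LPS and 53 and 17 for the difference. With at least 50 CPM, fewer genes were compared, with 689 and 757 lower after LPS (wild type and labelled Trpv4-null), 1 higher between genotypes untreated and 3 under LPS.

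In the cluster named Macrophage alone, 11 genes were lower by the difference, Top2a was at -0.084 between genotypes untreated and the S phase median was -0.03 for LPS in wild type. Without cells called in S or G2/M phase these values were -0.096 for Top2a and -0.047 for S phase, and the G2 and M phase medians between genotypes were -0.001 untreated and -0.025 under LPS, which the removal of dividing cells shows by construction. Without cells at 5% or more mitochondrial UMIs, 15 genes were higher untreated and 11 lower by the difference, and with every cell weighted equally 14 and 10. Leiden clustering gave 11 clusters at resolution 0.5 and 15 at 1.0, against 9 by the authors, with 10 and 14 of them holding at least 95% of their cells from 1 treatment. Their adjusted Rand index with the authors' clusters was 0.105 and 0.108, so they group the cells differently, and the values within clusters were computed for the authors' clusters alone.

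Removal of doublets was not run, because the caller marked 1 cell. DESeq2, a mouse block and leaving out each mouse were not run, because no cell carries the name of a mouse. No paired analysis was possible because each group was 1 library and the cells carry no mouse number. Depth limits low genes most, with Trpv4 resting on 255 to 1049 UMIs per library.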

Other observations

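The tests in this part, on aryl hydrocarbon receptor targets and on hypoxia genes outside the fixed list, were set before their own values were seen, on patterns noticed in these data. Genes in the next paragraph that lie outside the fixed naming were chosen after their values were seen.

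Besides the groups already described, several macrophage surface and secreted genes differed between the genotype labels in both pairs. The folate receptor Folr2 had log2 ratios of 0.66 untreated and 0.75 after LPS, the coagulation factor F10 0.85 and 0.72, and the cationic amino acid transporter Slc7a2 -0.64 and -0.58. The growth factor Vegfa stood at 64.5 and 39.7 CPM untreated, and at 13.4 and 8.62 CPM after LPS, in the order wild type and labelled Trpv4-null. Galectin-3, Lgals3, was higher in all 8 clusters in both pairs (0.23 to 0.61 untreated and 0.66 to 0.92 after LPS). The prostaglandin synthase Ptgs2 stood at 7.41 and 19.7 CPM after LPS, higher in all 8 clusters (0.60 to 1.87). The transcription factor gene Hif1a stood at 177 and 122 CPM after LPS and was lower in all 8 clusters (-0.60 to -0.26), but at 109.2 and 109.0 CPM untreated. The potassium channel Kcnn4 stood at 35.1 and 21 CPM untreated and 80.8 and 86.2 CPM after LPS.

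Ahrr (7.89 and 26.2 CPM) and Tiparp (34.9 and 70.5 CPM), both targets of the aryl hydrocarbon receptor, were higher in the untreated library labelled Trpv4-null, and higher activity of that receptor is a candidate explanation. It was to be read from Cyp1a1, Cyp1b1, Nqo1 and Aldh3a1 where they reached 20 CPM. No target did, so the number of further targets higher by 0.5 or more was 0 and the question of aryl hydrocarbon receptor activity stays open. Nqo1 had a log2 ratio of 0.71 at no more than 3.79 CPM, and Cyp1a1, Cyp1b1 and Aldh3a1 were not in the count table.

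Glycolysis and hypoxia genes were lower after LPS in the library labelled Trpv4-null, and a weaker hypoxia response may account for it. Of Ndrg1, Ankrd37, Adm and Pdk1, only Ndrg1 reached 20 CPM, with a log2 ratio of -0.097, so the test rested on 1 gene and a lower hypoxia response cannot be told apart from other causes. Below 20 CPM, Pdk1 lay at -0.56 (19.7 CPM) and Ankrd37 at -0.66 (5.21 CPM), and Adm at 0.01 (0.114 CPM).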
